A study of Mus musculus with 8 samples.

How the data were processed

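Gene expression was measured on 8 Affymetrix mouse arrays, 4 labelled control and 4 labelled Bmi1. Per the labels, the cells were Dlk-positive hepatoblasts, the bipotent precursors of hepatocytes and bile duct cells, taken from livers of Ink4a-Arf-null embryos at day 14.5. They were sorted with magnetic beads, kept 12 to 18 h, transduced with EGFP or Bmi1, and grown with HGF at 50 ng/ml and EGF at 20 ng/ml. On day 28 of culture the transduced cells were purified by flow cytometry, and RNA equal to 10000 cells went through a 2-cycle amplification before hybridisation. The series describes 4 independent experiments.

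The deposited values are probe set intensities on a linear scale, 45101 on each array. The software that made them is not given in the sources used here. On every array the mean after trimming 2% at each end was 100, so the authors' values carry a global scaling per array. Of the probe sets, 64 were control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 are unnamed here. Symbols came from the platform annotation, updated through gene identifiers. For arrays, the number of arrays limits the precision.

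Values were taken as log2(value + 3.78), the constant being the median of all values divided by 4, so folds of dim genes are understated. The rule fixed beforehand was to centre each array on its median if the array medians differed by over 0.5 on the log2 scale. Over all probe sets they differed by 0.70, so centring was done, but on the median of the tested genes, which differed by 0.21 and would not have started it. This choice was made before any fit and after the array medians and the signals of Bmi1 and Sox17 had been seen. The rule's plainer reading is the median of all probe sets, which was expected to add noise to the tested genes. That reading and the values without centring are given as other settings. Genes named by a probe set with 1 symbol entered with the probe set of highest mean. Genes at or above the 40th percentile of mean level were kept, which left 10916 of 18193 genes.

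Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Differences are arrays labelled Bmi1 minus arrays labelled control. Of 31 gene lists, 26 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The test, the lists and most of the other settings were fixed before the data were examined. The rule for named genes took Bmi1, Cdkn2a, Cdkn2b and Sox17. It added up to 15 called genes with non-overlapping groups in each direction, by size of difference. From each list it took up to 4 called members, or the 2 with the smallest p. The rule was also applied to the fit with the replicate block, which it does not mention, and any other gene is said to have been chosen after its values were seen.

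Whether the replicate numbers pair the arrays was checked before the fits were compared. Deviations from the group means correlated at 0.53, 0.49, 0.50 and 0.68 between arrays of the same number, and every array correlated best with its own number in the other group. The Y-linked gene Eif2s3y was close within 3 pairs, with signals of 514 and 552 in pair 1, 216 and 225 in pair 3, and 106 and 115 in pair 4. In pair 2 it read 59.4 and 135, a ratio of 2.27, and Bmi1 2 lies nearer to control 4, so this gene does not place pair 2. Xist read 1031 and 774, 1615 and 1675, 921 and 798, and 585 and 872 in pairs 1 to 4. The Y-linked Kdm5d read 127 and 165, 53.7 and 65.5, 82.1 and 104, and 58.8 and 69.4, the same order of numbers in both groups. By Xist and by Kdm5d, controls 1, 3 and 4 each lay nearest to a Bmi1 array of another number. The sex-linked genes therefore do not settle the pairing. The difference between replicates 1 and 2 and replicates 3 and 4, described below, was not removed, so it adds to the correlations. They therefore tell less about which array is the partner among those with the nearer numbers. The pairing rests on these correlations, with that limit, and on the 4 experiments of the series. The main model has no block, as fixed, and values from the model with the replicate number as a block are given where they change a call.

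Replicates 1 and 2 stood apart from replicates 3 and 4. The BioC 3' hybridisation control read 274, 198, 231 and 227 on the former arrays and 111, 97.0, 118 and 119 on the latter. These are called run 1 and run 2 here. The run difference called 2651 genes in limma, and each run holds both groups equally. The interaction of run and group called 0 genes, with 301 at an unadjusted p under 0.05.

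Background was taken on each array as the 95th percentile of 27 control probe sets for Bacillus transcripts without spiked RNA. Where a probe set was below it on all arrays of a group, the fold is given as a bound against that level.

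The models were tested on simulated data. In 20 draws of 10916 genes for the comparison of the groups, 100 genes were changed by a log2 difference of 1 and 100 by 2. Without the block 26.0% and 76.3% were recovered on average (ranges 18 to 34% and 64 to 85%), with 0.45 false calls per draw. With the block 56.5% and 87.2% were recovered (48 to 61% and 77 to 93%), with 5.3 false calls per draw. The simulated arrays carried the pairing by replicate number, so the gain with the block was built in. It does not show that the block suits these arrays. Camera called the 1 list shifted in the simulation and 0 others. The noise was drawn independently for each gene, so this does not test camera where genes of a list move together. In the data the estimated correlation was 0.28 for the hepatocyte secreted proteins and 0.38 for the metabolic enzymes.

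Alternatives covered the blocks, the variance model, array weights, scaling, pseudocount, filter, choice of probe sets, and each array left out. Added after the data were seen were the values without centring, the replicate block under other scalings or without a pair, each run alone, and the replicate block with other list tests. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome build is given, so no coordinates are printed.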

Results

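The series asks what forced expression of Bmi1, a member of Polycomb repressive complex 1, does to hepatoblasts that lack the Ink4a-Arf locus, the best known Bmi1 target. It holds 4 arrays labelled control, from cells carrying EGFP, and 4 arrays labelled Bmi1, each from day 28 of culture and numbered 1 to 4. Values are array signal intensities, and 10916 genes were tested.

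Signal for Bmi1, the introduced gene, was not higher in the arrays labelled Bmi1. Its brighter probe set read 518 ± 218 in the arrays labelled control and 279 ± 60.01 in the arrays labelled Bmi1 (SD, n = 4 each), a log2 difference of -0.89 (SE 0.32). The limma adjusted p was 0.461, and 0.0248 with the replicate block. The other Bmi1 probe set read 216 ± 136 and 100.3 ± 25.4. Both were lower in the array labelled Bmi1 in 4 of 4 pairs. Both are annotated to 1 transcript accession, and the probe positions relative to the introduced sequence are not given in the sources used here. Directions are given by the labels. The Bmi1 signal is lower where they name the introduced gene, but without probe positions it cannot show whether they are wrong.

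Of the locus absent by genotype, the Cdkn2a probe set read 2.50 ± 2.76 and 6.11 ± 2.32, with 4 of 4 control arrays and 3 of 4 Bmi1 arrays at background. Cdkn2b, the neighbouring inhibitor of cyclin-dependent kinases, read 914 ± 192 in the arrays labelled control and 1079 ± 379 in those labelled Bmi1, a log2 difference of 0.12 (SE 0.25, limma adjusted p = 0.984). Sox17, a transcription factor of endoderm and of bile duct and endothelial precursors, fell at 1 of its 2 probe sets. The probe set whose name ends in _x_at, a mark of possible cross-hybridisation, read 37.7 ± 12.3 in the arrays labelled control and was at background on all 4 arrays labelled Bmi1, so its signal there was at least 5.93-fold lower. With each probe set tested by itself, it passed in limma (adjusted p = 0.0309, and 0.00694 with the replicate block). Leaving out any array but control 4 raised that p above 0.05, to at most 0.169. The other Sox17 probe set read 7.99 ± 6.01 and 9.02 ± 4.44. Sox17 lay under the level filter of the gene test.

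**Figure D1:**
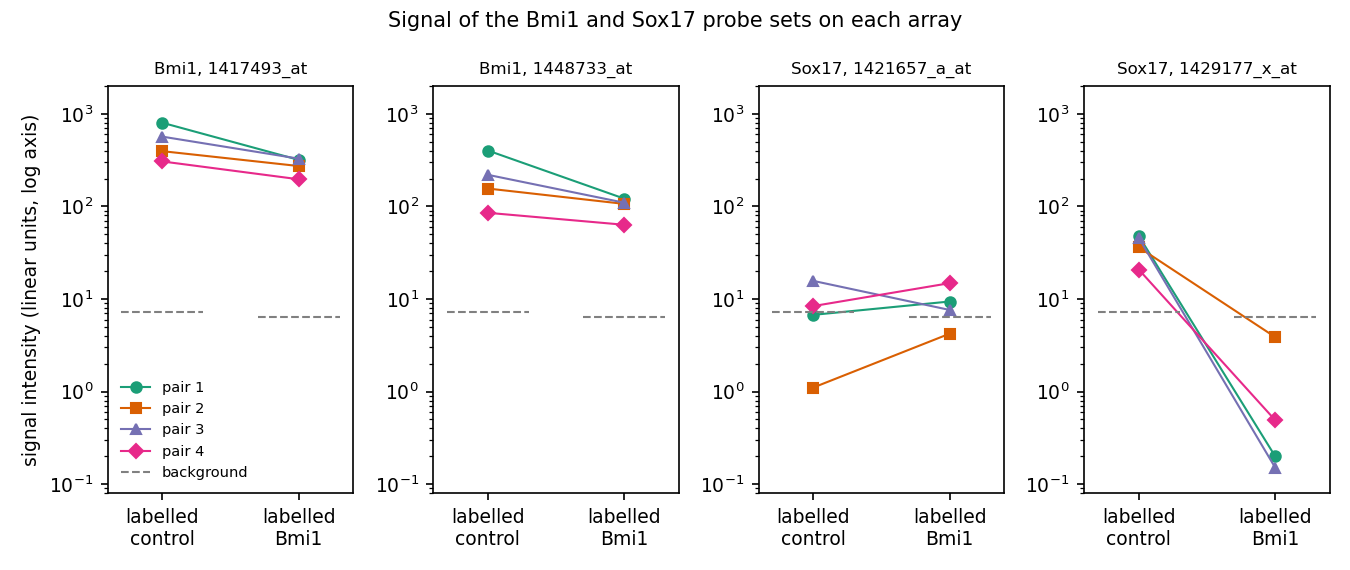
Signal intensity (log axis) of the Bmi1 and Sox17 probe sets on each array, with lines joining the 4 pairs and dashed lines at the mean background of each group. Both Bmi1 probe sets are lower in the array labelled Bmi1 in every pair, and the Sox17 probe set ending in _x_at, at 37.7 on average in the arrays labelled control, is below background on all 4 arrays labelled Bmi1.

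Between the groups, 12 genes rose and 6 fell in the arrays labelled Bmi1, all by at least 2-fold. The largest rises were those of Tcfl5, a helix-loop-helix transcription factor, from 15.5 ± 10.8 to 199.6 ± 65.1 (log2 difference 3.44, SE 0.39, limma adjusted p = 0.0298), and of the potassium channel gene Kcnk1, from 15.6 ± 15.05 to 166 ± 42.2 (3.35, SE 0.49, adjusted p = 0.0406). Camta1 (2.09), Crmp1 (2.06), Arfgef3 (1.79), Lgi2 (1.75), Ina (1.67), Tox2 (1.63), Scara3 (1.51) and Slc29a4 (1.16) rose as well, and so did St14 (3.99-fold) and Prdm16 (2.82-fold). St14 encodes the epithelial protease matriptase, Crmp1 and Ina are known from neurons, and Prdm16 is a transcriptional regulator. Ugt2b5, a glucuronosyltransferase of the liver, fell from 150.1 ± 38.0 to 23.9 ± 4.02 (log2 difference -2.53, SE 0.22, adjusted p = 0.00796). The sulfotransferase Sult2a2 (-2.44), the zinc finger factor Sp8 (-2.01), the canalicular export pump Abcc2 (-1.88), the gluconeogenic enzyme Pck1 (-1.74) and the flavin monooxygenase Fmo5 (-1.54) fell too. With the probe sets of a gene averaged, Camta1 (0.95), Tox2 (0.84) and Pck1 (-0.68) were under 2-fold and did not pass.

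These 18 calls compare with 853 genes at an unadjusted p under 0.05, where chance would give 546 for independent arrays. All 18 had groups that did not overlap, as did 5.33% of all tested genes, where the same assumption gives 2.86%. These arrays differ by run and correlate by replicate number, so neither value is the chance level here. With the replicate block limma called 363 genes, 149 higher and 214 lower, and kept all 18. With the run as a block it called 198, and within run 1 or run 2 alone it called 0, with 824 and 1012 at an unadjusted p under 0.05. Without the block, centring on the median of all probe sets, the plainer reading of the rule fixed beforehand, called 13 genes, 6 higher and 7 lower. Of the 18 it kept 7, which were Tcfl5, Kcnk1, Camta1, Crmp1, Arfgef3, Ugt2b5 and Sult2a2. Quantile normalisation called 6 genes higher and 1 lower and kept 6 of the 18, and no centring called 20 higher and 8 lower and kept all. With the block, quantile normalisation gave 158 higher and 175 lower, no centring 222 and 187, and centring on all probe sets 280 and 197, so which direction held more genes depends on the scaling. Centring on all probe sets moved the median difference of all tested genes from -0.03 to 0.11. Leaving out control 4 gave 20 genes, Bmi1 1 gave 3, Bmi1 4 gave 2 and control 1 gave 1. Of the 18 they kept 8, 1, 2 and 1. Leaving out control 2, control 3, Bmi1 2 or Bmi1 3 gave 0 in limma, with 671, 778, 869 and 625 genes at an unadjusted p under 0.05.

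**Figure D2:**
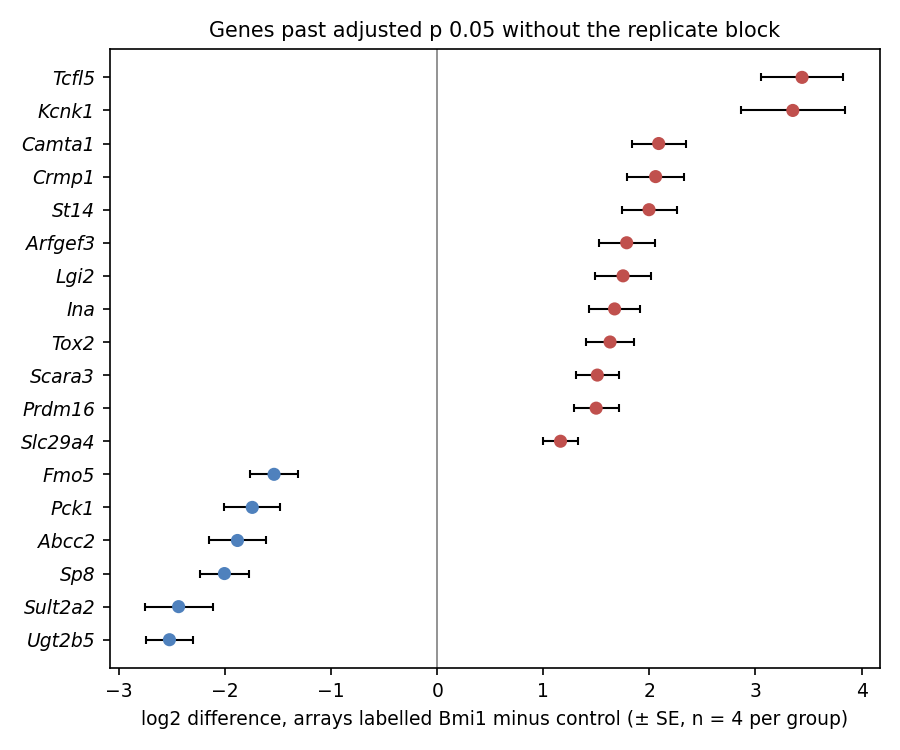
Log2 difference between arrays labelled Bmi1 and control for the 18 genes past the threshold without the replicate block, with bars of 1 SE (n = 4 per group). Differences run from 3.44 for Tcfl5 to -2.53 for Ugt2b5.

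Genes of the hepatocyte lists were lower in the arrays labelled Bmi1. All 27 tested metabolic enzymes had a lower mean there, with a median log2 difference of -1.55, and so did all 35 tested secreted proteins, with a median of -0.73. Without the block Pck1 was the only member called in either list. Adjusted over the list alone, 14 enzymes and 16 secreted proteins passed. With the replicate block 11 enzymes and 10 secreted proteins fell, and 23 and 27 adjusted over the list alone. Among them were Fbp1 of gluconeogenesis (-2.93, adjusted p = 0.00527 with the block and 0.0594 without), the cytochrome Cyp3a11 (-3.08, 0.0137 and 0.0651), the methyltransferase Bhmt (-2.58, 0.0109 and 0.327), the antithrombin gene Serpinc1 (-2.31, 0.0125 and 0.0524) and Itih4 (-2.21, 0.0165 and 0.225). The coagulation factor F10 (-1.97, 0.0201 and 0.243), Itih1 (-1.68, 0.0197 and 0.275) and the glucose phosphatase G6pc (-1.55, 0.0112 and 0.232) fell with the block too. Camera gave adjusted p = 6.7e-18 for the enzymes and 1.5e-17 for the secreted proteins. With an estimated correlation the adjusted p was 0.164 for each. The lists were lower in 4 of 4 pairs, and their medians within run 1 and run 2 were -0.98 and -1.52 for the enzymes and -0.60 and -0.78 for the secreted proteins.

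The 15 largest falls with the replicate block, among genes whose groups did not overlap, held Ugt2b5 and 4 members of the lists, Cyp3a11, Fbp1, Saa1 and Orm1. The other 10 did not pass without a block, and passed with the replicate block and with the run block. They were 3110039M20Rik (log2 difference -3.35, limma adjusted p = 0.00605), the cytochrome Cyp3a25 (8.03-fold lower, 0.0112), the vitamin E transfer protein Ttpa (-2.63, 0.01004), the transporter Slc6a13 (-2.63, 0.00527), the protease inhibitor Tfpi2 (-2.60, 0.0335), Fgl1 (-2.55, 0.0242), Apof (-2.53, 0.00605), Cyp2f2 (5.66-fold lower, 0.0106), the coagulation factor F13b (-2.48, 0.0097) and the complement gene Hc (-2.48, 0.0271). Without the block their adjusted p lay between 0.0835 and 0.225, and no list test covers them. Alb, Afp and Ttr, chosen after their values were seen, did not pass in either model. Over 31 other settings the log2 difference ran from -0.37 to -0.012 for Alb and from -0.29 to -0.00097 for Afp. For Ttr it ran from -0.32 to -0.0072, and 0 of these settings passed for any of them. Each range lay nearer to no change than the median of -0.73 of the secreted proteins. Their probe sets are among those whose signal may be saturated, so these values do not settle how far the genes fell.

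Liver transcription factors did not pass as a list. Of 19 tested, 10 were higher and 9 lower, with a median log2 difference of 0.03, a mean of -0.08 and camera pointing up (adjusted p = 0.793). Hnf4a, chosen after its value was seen, read 1214 ± 486 and 1031 ± 265. The bile acid receptor Nr1h4 fell with the replicate block (-1.38, adjusted p = 0.031, and 0.653 without). Of 15 biliary markers 10 were higher, with a median of 0.14 (adjusted p = 0.113). The surface protein Epcam (0.99, adjusted p = 0.022) and the cadherin Cdh1 (0.51, 0.0255) rose with the block, against 0.171 and 0.31 without it.

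**Figure D3:**
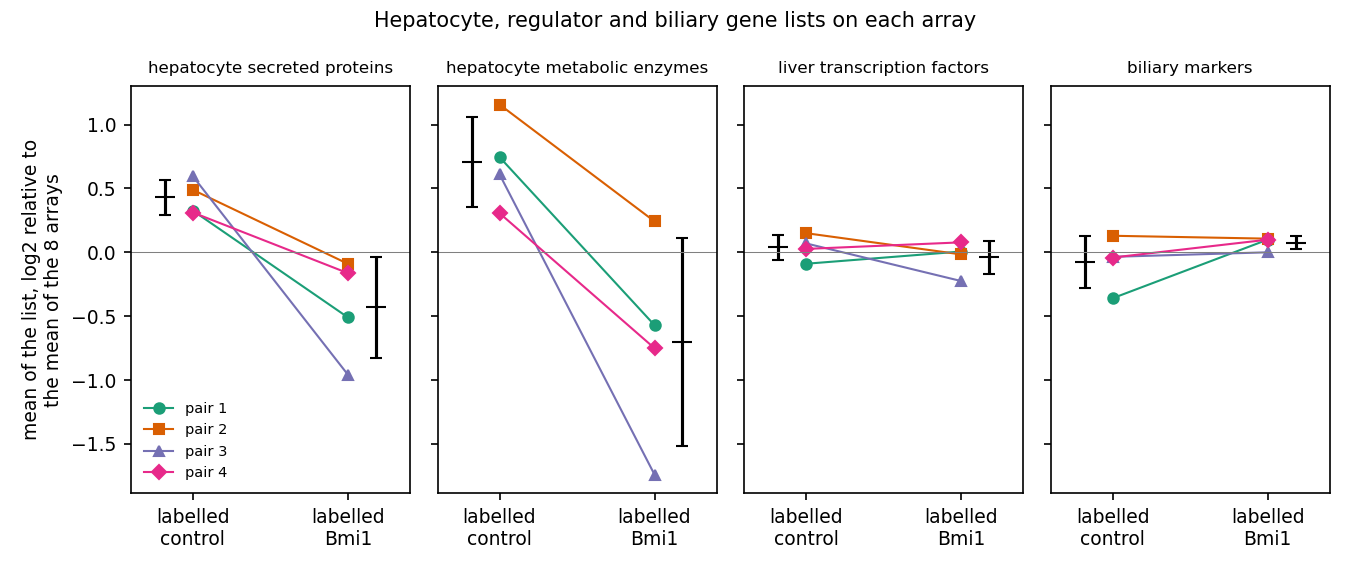
Mean of 4 gene lists on each array, in log2 units relative to the mean of the 8 arrays, with lines joining pairs and black bars giving the group mean and SD (n = 4). Both hepatocyte lists are lower in the array labelled Bmi1 in every pair, with means of 0.71 and -0.71 for the enzymes.

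Cell cycle genes were higher in the arrays labelled Bmi1 for 46 of 50 tested members, with a median log2 difference of 0.24 (camera adjusted p = 0.000211). The adjusted p was 0.655 with an estimated correlation, and with camera 0.269 when control 2 was left out and 0.435 with array weights. The list was higher in 3 of 4 pairs, and lower in pair 4 (-0.15). Ccnd1, the cyclin of early G1, rose with the replicate block (1.02, SE 0.09, limma adjusted p = 0.00605, and 0.156 without). Of 18 inhibitors and senescence genes 8 were higher and 10 lower (camera adjusted p = 0.793), and of 25 p53 targets 10 were higher and 15 lower (0.793). The stress-induced growth arrest gene Gadd45a fell with the replicate block (-1.07, limma adjusted p = 0.0162, and 0.895 without).

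No single Polycomb complex 1 member other than Bmi1 itself passed in either model. The list held 18 tested genes with a median of 0.19 (camera adjusted p = 0.0731, and 0.0514 with the replicate block). It passed in 3 of 35 other settings, pointing up with the run block (0.0329), with every probe set tested (0.0216) and without control 3 (0.0477), while with an estimated correlation the adjusted p was 0.319. The 11 members of complex 2 had a median of 0.06 (0.562). Among 22 tested developmental transcription factors often bound by Polycomb, 12 were higher and 10 lower (0.841), and 1 rose and 2 fell adjusted over the list alone. Tbx1, a T-box factor of the pharyngeal region, rose with the block (2.50, limma adjusted p = 0.0122, and 0.251 without). Of 33 Hox genes on the array 1 passed the level filter.

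Stem and progenitor markers did not move as a list, with 12 of 24 higher, a median of -0.05, a mean of 0.03 and camera pointing up (adjusted p = 0.772). The receptor tyrosine kinase Kit rose with the replicate block (1.66, limma adjusted p = 0.0179, and 0.0546 without), while the transporter Abcg2 fell (-0.61, 0.0347 and 0.289). Dlk1, the marker used to sort the cells, read 1324 ± 685 and 2242 ± 759 (0.80, adjusted p = 0.676 without the block and 0.0507 with it).

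Most tested members were lower in the NF-kB and acute phase, oxidative stress, and immediate early and unfolded protein response lists. Whether these falls are separate from those of the hepatocyte genes was not tested. In the NF-kB and acute phase list 22 of 23 members were lower, with a median of -0.93 (camera adjusted p = 4.6e-05; adjusted p = 0.39 with an estimated correlation). Of them 0 passed over all genes and 2 adjusted over the list alone, and with the replicate block 5 and 12. The acute phase genes Saa1 (-3.13, limma adjusted p = 0.0197 with the block and 0.132 without), Orm1 (-2.68, 0.0156 and 0.161), Saa3 (-1.62, 0.0197 and 0.943) and Crp (-1.17, 0.0319 and 0.327) fell with the block. So did the apoptosis inhibitor Birc3 (-0.93, 0.0407 and 0.421). Of 19 oxidative stress genes 17 were lower, with a median of -0.30 (camera adjusted p = 0.00285, and 0.39 with an estimated correlation). Gstm3 (-1.91, limma adjusted p = 0.0157) and Cdo1 (-1.78, 0.0391) fell with the block, against 0.262 and 0.513 without it. Camera gave 0.214 for this list when control 4 was left out. Immediate early and unfolded protein response genes were lower for 22 of 29 members, with a median of -0.19 (0.0209, and 0.164 with an estimated correlation). That call held in 23 of 35 other settings. It was lost without control 2 (0.0640), Bmi1 1 (0.0664) or Bmi1 4 (0.0559), with quantile normalisation (0.0664), centring on all probe sets (0.147), array weights (0.0770) and no level filter (0.117). Asns, a target of the stress response, fell with the block (-0.48, limma adjusted p = 0.0347, and 0.748 without). Mitochondrial respiratory chain genes were lower for 28 of 33, with a median of -0.08 (camera adjusted p = 0.0398, and 0.655 with an estimated correlation). Their call held in 11 of 35 other settings only. It was lost without control 3 (0.158), control 4 (0.547), Bmi1 1 (0.719) or Bmi1 2 (0.0868), with quantile normalisation (0.959), centring on all probe sets (0.733) and no centring (0.302).

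Fibroblast and stellate cell markers, which report cells from outside the epithelium, were lower for 26 of 29 members, with a median of -0.82 (camera adjusted p = 0.00819, and 0.655 with an estimated correlation). This rested on control 1, without which the adjusted p was 0.981, and was lost with array weights (0.923). Their median was -1.20 in run 1 and 0.15 in run 2. With the replicate block the smooth muscle actin Acta2 fell (-1.11, limma adjusted p = 0.0397, and 0.778 without) and Reln rose (1.55, 0.00761 and 0.408). All 6 mesothelial markers were lower, with a median of -0.57 (camera adjusted p = 0.068). That list passed in 18 of 34 other settings, among them the run block (0.0351), quantile normalisation (0.0286) and centring on all probe sets (0.00308), but not without control 1 (0.71) nor with an estimated correlation (adjusted p = 0.655). Its member Msln fell with the replicate block (-1.26, limma adjusted p = 0.0483, and 0.681 without).

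Endothelial, macrophage and erythroid lists had 4, 4 and 3 members above the level filter, too few for the list test as set. The endothelial members were higher in 4 of 4 pairs, with a mean log2 difference of 0.42 (95% interval -0.06 to 0.90), and Egfl7 rose with the replicate block (0.95, limma adjusted p = 0.0205, and 0.289 without). The erythroid members were higher in 4 of 4 pairs as well (mean 0.44, interval -0.01 to 0.88). The macrophage members were lower in 3 of 4 (mean -0.37, interval -1.44 to 0.70). With every probe set tested, camera called 15 endothelial probe sets up (adjusted p = 2.3e-05), while over 21 genes without the level filter it gave 0.742. Macrophage markers were lower at the higher pseudocount (6 genes, 0.0465) and did not pass in 3 other settings. Control 1 also had the highest Gapdh 3' over 5' ratio, 3.10, against 1.65 to 1.96 on the other arrays.

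**Figure D4:**
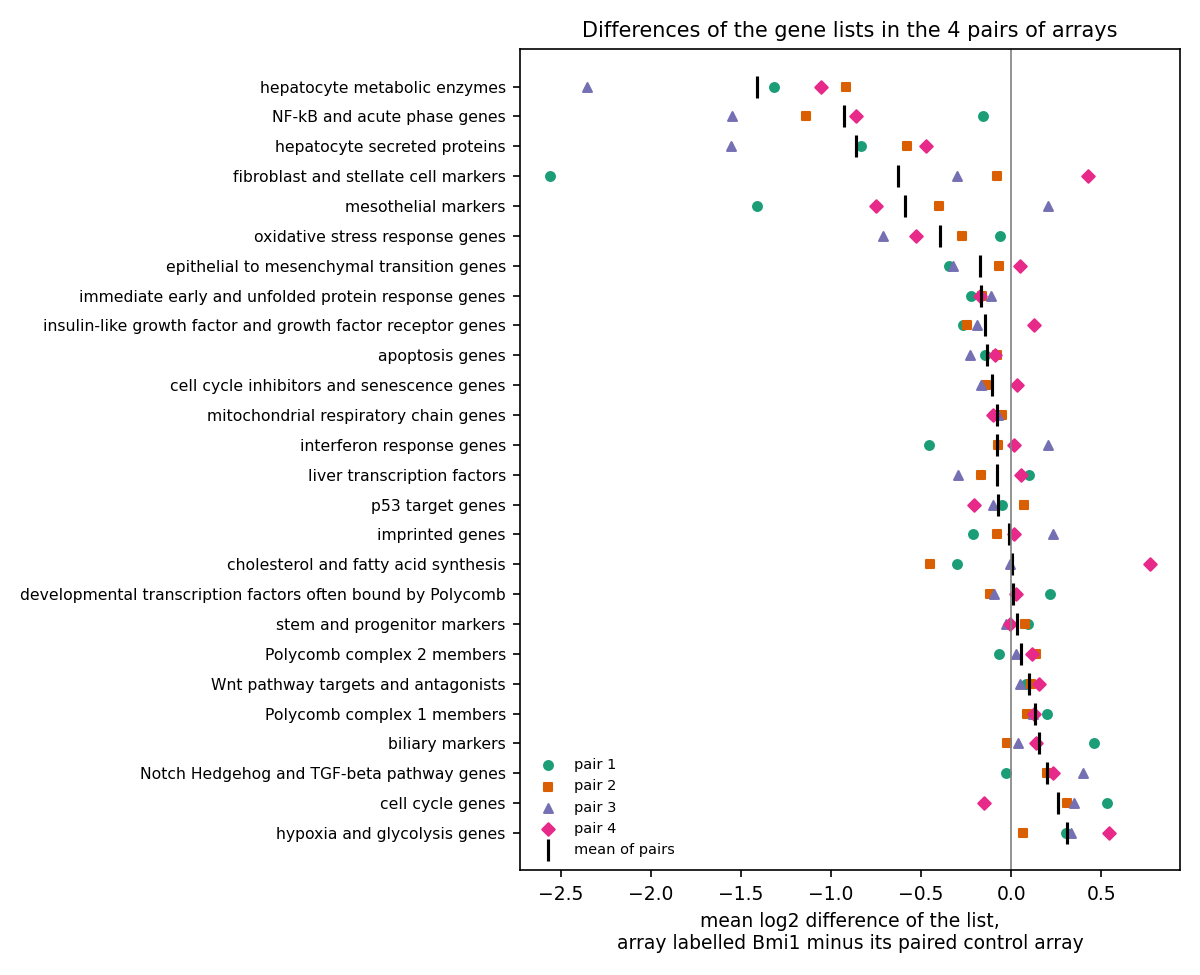
Mean log2 difference of each tested gene list within each of the 4 pairs, array labelled Bmi1 minus its paired control array, with a bar at the mean of the pairs. The hepatocyte lists lie below 0 in every pair, while fibroblast and stellate markers run from -2.56 in pair 1 to 0.43 in pair 4.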

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

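Tests chosen after the result was seen are the 3 on the Bmi1 signal and the splits for the hepatocyte genes.

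Bmi1 signal was lower in the arrays labelled Bmi1. Both probe sets were lower in 4 of 4 pairs, which argues against an exchange of 1 array only if they read the introduced sequence. They are annotated to 1 transcript accession, so they are not separate evidence. An exchange of all the group labels cannot be told apart from the labels as given, since 0 features of the tables other than Bmi1 name the arrays with the introduced gene. Whether the probe sets lie outside the introduced sequence stays open as well, since 0 columns of the annotation give probe positions. No biological explanation was tested.

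Of 232 groups of 4 arrays examined, 7 held an array far from the other 3 by the test of Dixon, where chance gives about 12. Spon1 was highest on Bmi1 3, with a gap of 0.894 of the range. The mean of the biliary markers was lowest on Bmi1 3 (0.926). The mean of the stem and progenitor markers was lowest on control 2 (0.886). The mean of Polycomb complex 2 members was highest on control 1 (0.866). The mean of the cell cycle genes was lowest on Bmi1 2 (0.879). The mean of the fibroblast and stellate cell markers was highest on Bmi1 2 (0.830). The Gapdh 3' over 5' ratio was highest on control 1 (0.860).

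Outside the gene test, 2 of 4095 probe sets unnamed here were called when each was tested by itself, and 38 with the replicate block. The one that rose went from a mean of 399.8 to 1259, a log2 difference of 1.61 (SE 0.22, limma adjusted p = 0.0489). The one that fell went from 195 to 31.8, a log2 difference of -2.52 (SE 0.35, limma adjusted p = 0.0489).

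Other groupings of the arrays bear on the counts of calls. Of the 35 splits into 4 and 4, 2 gave as many genes as the 18 of the labels, so chance is not excluded by this count. The other split follows the runs and called 2148 genes, a structure of the samples that is balanced between the groups. Among the 8 splits that part all 4 pairs, as the labels do, the others called 0 genes. They held 29 to 214 genes at an unadjusted limma p under 0.05, against 853 for the labels. Splits that part 2 pairs held up to 1473, so the size of that count depends on how a split treats the pairs. For the 10 gene lists called, 3 of the 35 splits gave as many, with 11 in the highest other, so chance is not excluded. Among the 8 splits that part all 4 pairs, the highest other called 7 lists. For the hepatocyte genes, a median difference as large in size as the 0.88 of the labels was reached by 2 of the 35 splits, with 0.90 in the other, so chance is not excluded by its size. The split with 0.90 parts 2 pairs. Among the 8 splits that part all 4 pairs the largest other median was 0.67, but 8 splits are too few for a share under 0.05. All 62 genes went one way in the labels' split only, and the highest other had 61. Exchanging the arrays inside the pairs gives 8 groupings with the replicate block, too few for a share under 0.05. The labels gave 363 genes there, reached by 1 grouping, and the highest other gave 0.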

How the results depend on the processing

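Settings without centring, the replicate block under another scaling, without a pair or with another list test, and each run alone were added after the data were seen. Where a value moved, the cause was not tested, except that leaving out arrays or a run leaves fewer samples.

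Against 18 genes called (12 higher, 6 lower, 18 at 2-fold), the replicate block gave 363 (149, 214, 243) and the run block 198 (95, 103, 155). Array weights gave 37 (24, 13, 36), quantile normalisation 7 (6, 1, 7), a pseudocount equal to the median 35 (24, 11, 35), no centring 28 (20 higher, 28 at 2-fold) and the 60th percentile filter 0, with 442 at an unadjusted p under 0.05. Centring on all probe sets called 13 (6 higher, 7 lower) and kept 7 of the 18, and testing every probe set called 12 (7 higher, 5 lower) and kept 7. Leaving out 1 array gave 0 to 20 genes, 0 to 13 higher, 0 to 7 lower and 0 to 20 at 2-fold, and kept 0 to 8 of the 18. Within run 1 and within run 2 limma called 0.

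In the same order, ending with genes called with a 2-fold difference, the replicate block gave 409 (222, 187, 276) without centring, 333 (158, 175, 240) with quantile normalisation and 477 (280, 197, 368) with centring on all probe sets. Without pair 1 it gave 187 (83, 104, 151), without pair 2 140 (64, 76, 132), without pair 3 94 (31, 63, 90) and without pair 4 207 (66, 141, 172). It kept all 18 genes except without pair 3, where it kept 14.

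The Bmi1 difference stayed negative in all 31 alternatives, from -1.13 to -0.62, with adjusted p from 0.0248 to 0.939. It passed with the replicate block (-0.89), and with the block without centring (-0.82), with quantile normalisation (-0.82) and without pair 1 (-0.71).

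Of the 10 lists called, 0 held with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, and 1 with the block and fry, the immediate early and unfolded protein response genes. The replicate block with camera also called 10. Over 35 other settings the hepatocyte, acute phase and hypoxia calls held in 31 each, all with camera at its preset correlation. They were lost in all 4 tests with an estimated correlation or fry. The estimated correlation was 0.28 for the secreted proteins, 0.38 for the enzymes, 0.31 for the acute phase list and 0.29 for the hypoxia list. The 31 settings do not test the preset correlation, so they do not show that these calls hold where genes of a list move together. The Notch, Hedgehog and TGF-beta call held in 29 (lost within run 1, 0.165, and with the block without pair 3, 0.0742), oxidative stress in 29 (within run 1, 0.391), cell cycle in 28 and fibroblast and stellate markers in 26. Lists not called without the block passed in some settings: cholesterol in 6, in both directions, Wnt in 3 (lowest adjusted p = 0.00251, array weights), growth factor receptors in 2 and biliary markers in 1 (within run 1, 0.0431).

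For the 18 genes called and the Sox17 probe set tested by itself, 323 values in other settings passed, 238 did not and 0 changed sign. Sizes shrank by over 1.5 times in 5 of the 18. With the probe sets of a gene averaged, the log2 difference of Camta1 was 0.95 (limma adjusted p = 0.198), the log2 difference of Tox2 was 0.84 (0.606) and the log2 difference of Pck1 was -0.68 (0.334). With a pseudocount equal to the median, the log2 difference of Sult2a2 was -1.62 and the log2 difference of Sp8 was -1.30, and both passed. For the other named genes, 1537 stayed uncalled, 421 passed and 4 changed sign. Their sizes moved as well. Over the other settings the log2 difference ran from -1.57 to -0.063 for Gadd45a and from -2.49 to -0.58 for Saa3. It ran from -1.66 to -0.38 for Acta2 and from 0.97 to 2.60 for Slc2a3. The log2 difference of Igf1 was 0.40 with array weights. The log2 difference of Cdkn2b was -0.049 with the block without pair 4, -0.31 within run 1, and -0.043 to 0.27 with 1 array left out. Genes near background, such as Sox17, are limited by signal over background.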

Other observations

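Tests chosen after the result was seen are those on cells from outside the liver epithelium and on biliary-type cells. The list of neuronal genes was written after some called genes had been seen and before its own members were.

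Genes of hypoxia and glycolysis were higher in the arrays labelled Bmi1 for 19 of 24 members, with a median log2 difference of 0.16 (camera adjusted p = 6.9e-05, and 0.39 with an estimated correlation), and in 4 of 4 pairs. Over all genes 0 passed and adjusted over the list alone 2 rose. The glucose transporter Slc2a3 (2.20, limma adjusted p = 0.00527) and the kinase Pdk1 (0.79, 0.0284) rose with the replicate block, against 0.12 and 0.103 without it. In the Notch, Hedgehog and TGF-beta list 18 of 32 members were higher, with a median of 0.03 (camera adjusted p = 0.00716, and 0.164 with an estimated correlation). The Notch target Nrarp (1.14, limma adjusted p = 0.00645) and the Notch ligand Jag2 (0.95, 0.0407) rose with the block, against 0.194 and 0.302 without it.

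Among the largest rises with the replicate block that did not pass without a block were Doc2b (2.30, limma adjusted p = 0.0162), Tesc (2.20, 0.0112), Dcdc2a (2.18, 0.0065), Septin3 (2.12, 0.0122), Spon1 (3.999-fold, 0.0119) and Mapk8ip2 (1.93, 0.0217), with adjusted p between 0.0594 and 0.206 without one. They passed with the run block too. Other genes that rose with the block were Spint1 (2.29, limma adjusted p = 0.00527), an inhibitor of epithelial proteases such as St14, the receptor Ror2 (2.18, 0.0219), Wnt7b (2.46-fold, 0.0225), the tight junction gene Ocln (0.70, 0.0222) and the imprinted RNA Meg3 (0.65, 0.0314). Without the block their adjusted p lay between 0.0632 and 0.67. The imprinted gene Phlda2 (1.18, 0.0386 and 0.735 without) and the receptor Fgfr1 (0.73, 0.0431 and 0.486) rose with the block. Igf1 (-1.14, 0.0348 and 0.954), Ccn4 (-0.86, 0.0179 and 0.771) and the apoptosis gene Cideb (-0.73, 0.0245 and 0.625) fell with it. Cholesterol and fatty acid synthesis genes went apart between the runs, with medians of -0.16 and 0.35, and did not pass as a list (camera adjusted p = 0.772). Other lists that did not pass camera were Wnt targets and antagonists (adjusted p = 0.154), transition of epithelium to mesenchyme (0.562), growth factor receptors (0.562), apoptosis (0.772), imprinted genes (0.793) and interferon response (0.841). The imprinted genes had a median of -0.05 while camera pointed up.

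Scaling is argued against as the source of the lower hepatocyte genes, since the median over the 62 genes stayed at or below -0.74 under 3 other scalings, against -0.88. RNA quality was judged by the Gapdh 3' over 5' ratio, lower in the array labelled Bmi1 in 2 of 4 pairs, while the hepatocyte genes were lower in all 4. The log2 difference of the ratio was -0.66, 0.07, -0.13 and 0.02 in pairs 1 to 4. Its mixed signs rest on 2 small values, so they cannot decide RNA quality. In pairs 2 and 4, where this ratio hardly differed, the mean difference of the hepatocyte genes was still -0.73 in each. Cells from outside the liver epithelium would lower liver transcription factors alike if these factors were confined to the epithelium, which was not tested. The factors' mean pair difference had a 95% interval from -0.37 to 0.21, above -0.55, which is 50% of the hepatocyte mean of -1.10. Of the factors 10 were higher and 9 lower. A list with members going both ways cannot decide the share of such cells. Markers of such cells went both ways too. The mean pair difference was 0.42 for the 4 tested endothelial and 0.44 for the 3 tested erythroid members, each higher in 4 of 4 pairs. It was -0.63 for fibroblast and stellate, -0.59 for mesothelial and -0.37 for the 4 tested macrophage markers, each lower in 3 of 4 pairs. The 95% interval of each of these lists included no change, so they do not decide the share of such cells either. A larger share of biliary-type cells cannot be told apart, since the mean pair difference of the biliary markers was 0.15 with an interval from -0.19 to 0.49.

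The signals of Alb, Afp and Ttr, which did not pass, may be limited by saturation. Across the 62 hepatocyte genes, which are not independent replicates, signal and difference had a Spearman rho of 0.43 (permutation p = 0.00062). Among the 32 with a control signal under 1000 it was -0.20 (permutation p = 0.27), so the relation was not seen below the bright range. The control signal sets this cut and also enters the difference with a minus sign, which favours a rho below 0. The test therefore does not settle saturation. No biological explanation was tested.

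A hypothesis from the called genes Ina and Crmp1 is that genes of neurons rose as a class. Of 23 tested genes of a neuronal and neuroendocrine list, 14 were higher, with a median of 0.31. Camera gave p = 0.000703 without the replicate block and 0.00436 with it, and p = 0.0317 and 0.0733 with an estimated correlation. Single members called were 0 without the block and 2 with it, Nsg1 and Dpysl5. The list was higher in 4 of 4 pairs. These values are consistent with a modest shift, found and tested on the same arrays.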
